A study of Equus asinus x Equus caballus and Equus caballus and Equus asinus with 15 samples.

How the data were processed

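Allele counts at SNPs were compared in chorionic girdle, the invasive trophoblast band of the equine placenta, from 15 conceptuses at gestation day 33 or 34. Per the labels, 5 were horses, 3 donkeys, 6 mules (donkey father, horse mother) and 1 a hinny (horse father, donkey mother). Per the series design each library is an individual sample, and each was placed in its group by its source label. Replicate numbers were given in accession order and pair no samples. The labels give the horses as 1 male at day 33 and 4 females at day 34, the donkeys as 2 males and 1 female at day 33, the mules as 1 male and 5 females at day 33 and the hinny as a male at day 33. Species, sex and day are therefore partly mixed in every comparison that involves the horses.

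Libraries were prepared from total RNA with an mRNA sequencing kit, per the labels' protocols, and TopHat is named in the submitters' processing notes. The TopHat version, the genome build, the SNP discovery method, the filters and the strandedness are not given in the sources used here, so positions are printed as the files give them. The values deposited by the authors are estimated counts per SNP, with a coverage column equal to the sum of the reference count and the alternative count. They are multiples of 0.5 and are not normalized. The reference allele is the horse allele and the alternative allele the donkey allele, as the horse and donkey libraries show. The files pair no SNP with a gene, and no annotation was used here, so no gene is named, and reads shared between paralogous sequences cannot be recognised.

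The horse, donkey and hinny files list 67233 SNPs and the mule files 61895 of these. SNPs counted as informative when the pooled horses had at least 10 counts with a horse-allele share of at least 0.95 and the pooled donkeys at least 10 counts with a share of at most 0.05. Of the SNPs listed in every library, 50420 passed: 48712 autosomal, 885 on the X chromosome, 241 mitochondrial and 582 unplaced. A further 10407 were under the pooled minimum, and 1068 were not species-specific. Because the SNPs were chosen this way, the low share of the other species' allele in horses and donkeys is partly built in. The SNPs not listed in mules had at most 40 pooled horse counts but up to 1895 pooled donkey counts, so the lists leave out mainly sites with little horse expression.

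Total counts per library ran from 517510 in mule 1 to 3724259 in mule 2. The median count per informative SNP ran from 4 to 27.5, so the share at a typical SNP in a single animal is imprecise, and the tests draw on several animals. Shares of a single library are given with 95% Wilson intervals. The labels mention no molecular identifiers, so reads may not be independent molecules, and intervals and floors of 3 counts cover counting error only. Where counts are summed over SNPs, a read is counted at each SNP it covers. Intervals and floors of such sums are then too narrow, and they leave out the spread between SNPs. Pairs of replicates held identical counts at no more than 5.01% of the SNPs with a count in either, and no library was treated as a duplicate.

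The design planned tests of genes. Without gene names the SNP became the unit of every test, and results are also given per locus, meaning informative SNPs joined while gaps were at most 10000 bases. Locus sums were chosen after the data were seen. SNPs within 1 transcript share reads, so counts of SNPs overstate the number of independent changes. Counts were rounded to whole numbers before model fitting, with multiples of 0.5 going to the even number.

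Allelic tests used edgeR 4.0.16 quasi-likelihood fits (glmQLFit and glmQLFTest) in R 4.3.3, with the horse and donkey counts of an animal as 2 columns, an animal term, and the animal's total as the library size of both columns. Tests covered autosomal SNPs with at least 10 counts in at least 4 mules, and in the hinny too for the parental test. The parental test was the difference of the allelic ratio between mules and hinny. A called SNP was paternal when the donkey allele was higher in mules and the horse allele in the hinny, maternal in the opposite case, and undirected otherwise. It was near-complete when the lower allele was at most 10% in both crosses. Since there is 1 hinny, this test assumes that hinnies vary as mules do.

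Total counts (horse plus donkey allele, mitochondrial SNPs left out) were fitted in all 15 libraries with TMM factors, filterByExpr and a mean per group. The contrasts were donkey minus horse, mule minus the mean of horse and donkey, and hinny minus mule. For cis and trans differences, the horse over donkey ratio between species was set against the ratio of the alleles in mules in the same kind of fit. That fit had a mean per group and no animal term. Both allele columns of a mule thus entered as separate libraries, and their pairing within the animal was not used. P-values were adjusted by Benjamini-Hochberg within each contrast, with 0.05 as the threshold. Mean shares were compared with 50% by exact two-sided sign-flip tests over animals.

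All comparisons, their tests and most alternatives were fixed before the data were examined, as was the rule for naming SNPs. For the parental test it took the 8 paternal and 8 maternal SNPs of lowest p. For the allelic test it took the 10 SNPs per allele with the largest ratio and the same direction in every mule with at least 10 counts, and the 5 deepest. For totals it took 8 per direction, with a mean log2 count per 1000000 of at least 4 and no overlap between groups. Named SNPs are reported here by region. Alternatives covered SNP filters, count minimums, normalization, DESeq2 1.42.0, Fisher's exact test on pooled counts, sex, day and leaving out each library. Fixed lists of imprinted genes, of X inactivation genes, of pathways and of cell type markers need gene names and are not analysed here.

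The fits were tested on simulated data with 200 changed SNPs each. For alleles in mules (23392 SNPs), 23 of 100 changes of log2 ratio 1 and 90 of 100 of log2 ratio 2 were recovered. For mules against the hinny (22116 SNPs), 100 of 100 changes with 5% from the lower allele and 46 of 100 with 25% were recovered. For donkeys against horses (49062 SNPs), 19.2% of changes of log2 2 and 80.0% of log2 4 were recovered. For mules against the parental mean (49070 SNPs) these shares were 40.4% and 90.8%, for the hinny against mules (49034 SNPs) 4.04% and 38.8%, and for species against allelic ratios (39249 SNPs) 5.49% and 60.6%. At most 7 unchanged SNPs were called in any of them. Shares and exact tests were computed in Python 3.11.15 with scipy 1.17.1, and plots with matplotlib 3.10.9.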

Results

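Allele counts from RNA sequencing of the chorionic girdle were available for 5 horse, 3 donkey, 6 mule and 1 hinny conceptuses. Mules carry a paternal donkey genome and a maternal horse genome, and the hinny carries the reverse, so the 2 crosses separate the effect of an allele's species from that of the parent it came from. Total allele counts were 2176987 to 2865918.5 in the horses, 978428 to 3248857.5 in the donkeys, 517510 to 3724259 in the mules and 2880092.5 in the hinny. Mule 1 was the shallowest library, with a count at 74.1% of its SNPs. Horse 3 had the lowest TMM factor, 0.739, and the lowest median correlation with the other libraries over SNPs, 0.499.

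Across the autosomes the horse and donkey alleles were nearly balanced in the hybrids, with a small excess of the horse allele. The horse allele made up 52.3% ± 0.441 (SD, n = 6) of autosomal allele counts in mules, and it exceeded 50% in 6 of 6 animals (exact two-sided sign-flip test, p = 0.03125, the smallest the design allows). In the hinny it made up 50.7% (95% Wilson interval 50.6 to 50.7). Both shares include abundant SNPs of chromosome 12, described below, with almost only the maternal allele. They raise the share of mules and lower that of the hinny. The median SNP stood at 50% in each mule and at 51.1% in the hinny. At the same SNPs the donkey allele made up 0.0270% ± 0.0241 (SD, n = 5) of counts in horses, and the horse allele 0.181% ± 0.00697 (SD, n = 3) in donkeys.

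Mitochondrial transcripts came from the maternal genome in every mule with mitochondrial counts. In mules 2 to 6, the horse allele made up 99.98% ± 0.0113 (SD, n = 5) of counts at 241 mitochondrial SNPs, with 294001 horse and 85.5 donkey counts in mule 2. Mule 1 and the hinny are listed at 0 at every one of these SNPs, so the maternal donkey mitochondria of the hinny could not be examined. Mitochondrial SNPs took 3.33% to 19.4% of the counts in the other libraries, the latter in horse 3.

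The comparison of alleles within mules asks which transcripts differ between the donkey and the horse genome in a shared cell environment. Of 23392 autosomal SNPs tested, 1257 had more horse-allele counts and 1116 more donkey-allele counts at an adjusted p under 0.05 in edgeR's quasi-likelihood test. They lie in 472 and 473 loci. With allele-specific library sizes, which centre each animal on equal alleles, the split was 990 against 1556. Fewer SNPs reached the count minimum without mule 2, 3 or 6, and the horse-higher and donkey-higher calls were then 739 and 605, 594 and 474, and 682 and 556.

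Among the called SNPs, the median horse share was 74.6% in mules and 71.9% in the hinny where the horse allele was higher, and 26.7% and 31.8% where the donkey allele was higher. Of the 2282 called SNPs with at least 10 counts in the hinny, 2063 (90.4%) lay on the same side in the hinny and 202 on the other side. The strongest imbalances were largely of the second kind. Of the 10 named SNPs with the largest horse excess, 9 lay in regions where the hinny expressed the opposite allele, and so did 9 of the 10 with the largest donkey excess. The exception with a horse excess, at position 3373398 of chromosome 20, had 100% horse allele in 6 of 6 mules (1587 counts, which allows up to 0.189% donkey allele) and in the hinny (exact binomial interval 98.9 to 100). Its log2 ratio of horse over donkey was 3.94 between species and 11.54 between the alleles of mules. The genotypes of the donkey parents were not analysed here, so a donkey allele absent from a parent cannot be told from a silent allele. The exception with a donkey excess, at 32451571 of chromosome 20, had 0.164% horse allele ± 0.328 (SD, n = 4) in mules, and it had 4 counts in the hinny, too few to test. Of the 5 deepest SNPs, 4 lay in the maternal region of chromosome 12 described next. The fifth, at 18963486 of chromosome 10, had 46.4% horse allele ± 9.86 (SD, n = 6; adjusted p = 0.564) in mules and 42.6% in the hinny.

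The comparison of mules with the hinny asks which transcripts follow the parent, not the species. Of 22116 autosomal SNPs tested, 71 favoured the paternal allele, 38 favoured the maternal allele and 36 differed without a change of side. For 59 of them, 26 paternal and 33 maternal, the switch was near-complete. The directed calls formed 44 clusters, 35 paternal and 9 maternal, of which 10 held at least 3 called SNPs. Near-complete SNPs lay in 5 paternal and 6 maternal clusters. Of the 71 paternal calls, 40, in 30 loci, had horse allele alone in the hinny but more than 10% in mules. The genotype of the hinny's mother may be the source at many of these loci, as described below. The larger number of paternal calls is therefore not evidence of more paternal expression. Shares of a cluster are taken over its called SNPs. The hinny is a single animal, so its values have no replicate check.

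On chromosome 12, a maternal and a paternal cluster lay close together. Between 30527666 and 30529524, all 10 tested SNPs were maternal: the horse allele made up 99.9% ± 0.0846 (SD, n = 6) of 354244 counts in mules and 3.12% (95% Wilson interval 3.00 to 3.24) of 80196.5 counts in the hinny. Single SNPs of this cluster ran from 0.986% to 5.45% in the hinny, so the interval of the sum understates the spread. Between 30630670 and 30639999, 101146 bases further, 16 of 17 tested SNPs were paternal, with 0.694% ± 0.221 (SD, n = 6) horse allele in mules and 99.99% in the hinny (99.97 to 99.997). The SNP not called, at 30631063, had 33.6% in mules and 100% in the hinny, and the sum over all 18 SNPs of the locus was 2.78% in mules. The lowest adjusted p-values in these clusters were 7.2281e-08 and 1.1762e-08, the latter at CUHSNP00191771. A further maternal cluster lay at 31274426 to 31275280, where 7 of 7 tested SNPs had 100% horse allele in every mule (7121 counts, which allows up to 0.0421% donkey allele) and 4.13% in the hinny (3.22 to 5.202). Outside chromosome 12, all 11 tested SNPs at 37367729 to 37372949 of chromosome 27 were maternal, with 99.8% ± 0.262 (SD, n = 6) horse allele in mules and 1.79% in the hinny (1.53 to 2.11). All 6 at 85047675 to 85060591 of chromosome 4 were paternal, with 1.35% ± 0.883 (SD, n = 6) in mules and 100% in the hinny (99.8 to 100). The 16 named SNPs of this comparison all fell in clusters listed here. With DESeq2, 2 of these 16, both on chromosome 27, were no longer called.

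**Figure D1:**
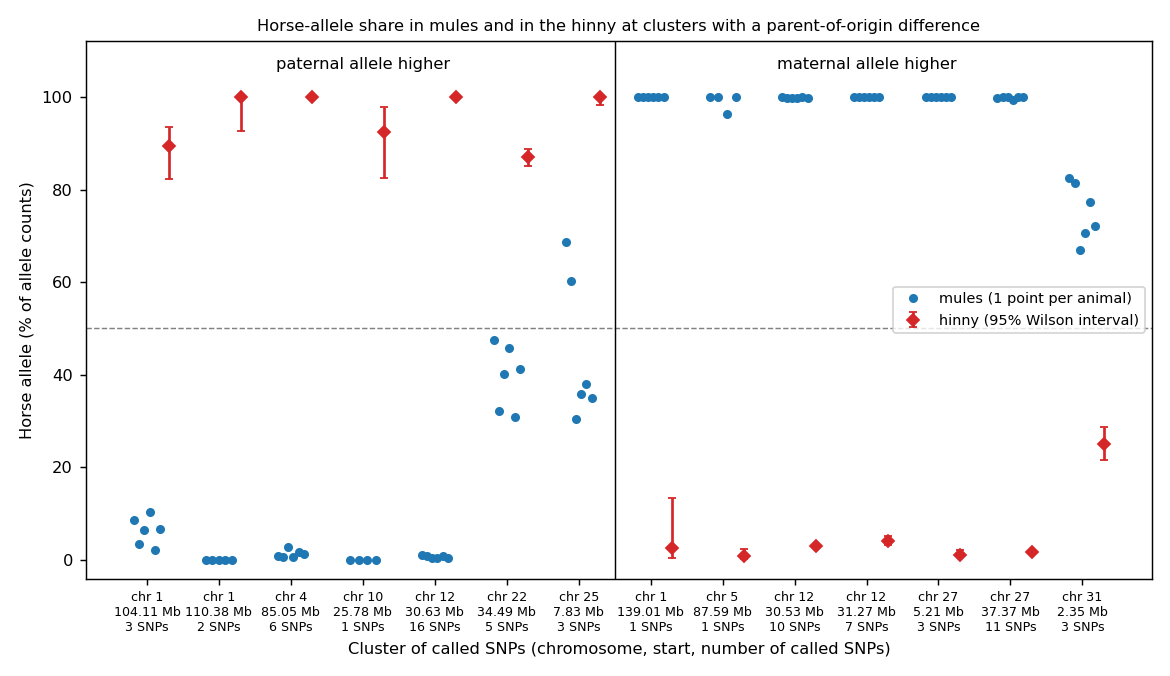
Horse-allele share, in percent of allele counts, at the 14 clusters with at least 3 called SNPs or a near-complete switch. Blue points are single mules and red diamonds the hinny with its 95% Wilson interval. In the cluster at 30630670 of chromosome 12, the mules lie between 0.464% and 0.973% and the hinny at 99.99%.

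**Figure D2:**
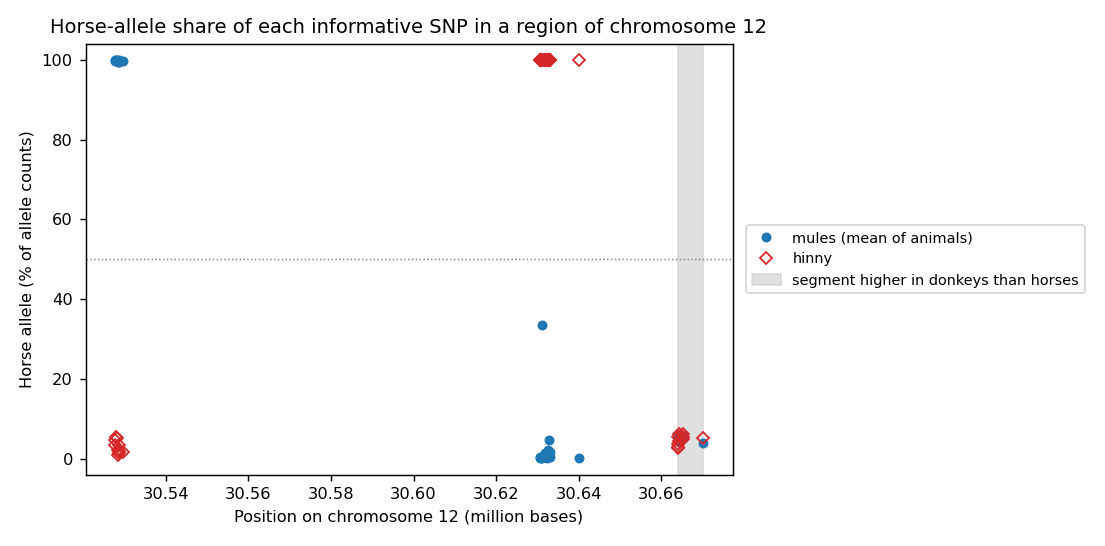
Horse-allele share of each informative SNP along a region of chromosome 12 holding the maternal cluster (30527666 to 30529524), the paternal cluster (30630670 to 30639999) and, shaded, the segment with higher counts in donkeys than horses (30664012 to 30670112). Blue points are means over the mules with at least 10 counts and red diamonds the hinny; in the shaded segment both crosses lie on the donkey side.

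Smaller clusters showed the same kind of switch. On chromosome 27, 3 of 3 tested SNPs at 5205596 to 5205631 had 100% horse allele in every mule (2787 counts, which allows up to 0.108% donkey allele) and 1.05% in the hinny (0.566 to 2.19). On chromosome 1, 3 of 7 tested SNPs at 104108798 to 104110265 were paternal, with 6.30% ± 3.11 (SD, n = 6) in mules and 89.5% in the hinny (82.2 to 93.5). Of 3 tested SNPs at 110378522 to 110378552 of chromosome 1, the outer 2 were paternal and had no horse counts among 276.5 counts in the mules that reached 10 counts, which allows up to 1.08%, and 100% horse allele in the hinny (92.6 to 100). The SNP between them, at 110378543, had 16.7% in mules and was not called. Near-complete switches at a lone SNP were found at 139012615 of chromosome 1 and 87593163 of chromosome 5, both maternal, and at 25781940 of chromosome 10, paternal. On chromosome 1 the hinny had 2.60% horse allele of 38.5 counts (0.466 to 13.5), and on chromosome 5 0.788% of 380.5 (0.269 to 2.30). On chromosome 10 it had 92.5% of 46.5 counts (82.5 to 97.8). The intervals on chromosomes 1 and 10 reach past the bound for a near-complete switch. Summed over its locus of 13 SNPs, the hinny had 87.9% on chromosome 10, which was not near-complete.

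Partial differences appeared in other clusters. At 34493707 to 34496406 of chromosome 22, 5 of 8 tested SNPs were paternal, with 39.6% ± 6.84 (SD, n = 6) horse allele in mules and 87.0% in the hinny (85.0 to 88.8). At 2351627 to 2368751 of chromosome 31, 3 of 24 tested SNPs were maternal, with 75.2% ± 6.23 (SD, n = 6) in mules and 25.02% in the hinny (21.6 to 28.8). At 7828660 to 7828900 of chromosome 25, 3 of 23 tested SNPs were paternal, with 44.7% ± 15.7 (SD, n = 6) in mules and 100% in the hinny (98.3 to 100). That last pattern, horse allele alone in the hinny but more than 10% horse allele in mules, covered 40 of the 71 paternal calls, in 30 loci. At the other SNPs of the same locus, the hinny had under 60% horse allele in 23 of 29 such loci, and 70% or more in 4. Among these 4 were the locus at 34493707 of chromosome 22 with 82.2% (95% Wilson interval 79.9 to 84.2) and that of chromosome 25 with 97.2% (95.9 to 98.1). The mules had 58.0% ± 15.01 (SD, n = 6) at these other SNPs of chromosome 25, and the sum over that locus, 55.3% in mules, differed from the hinny without a change of side. With counts summed over each locus, 10 paternal and 11 maternal loci were called among 5462, and 4 and 7 of these were near-complete.

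X-linked transcripts came mostly from the maternal X in the males and from both X chromosomes in the female mules. In the male mule the horse (maternal) allele made up 96.6% of counts at 885 X SNPs (95% Wilson interval 96.1 to 97.0). In the male hinny the donkey (maternal) allele made up 93.2%. The 5 female mules had 68.7%, 31.9%, 27.9%, 48.7% and 38.0% horse allele, a mean of 43.0% ± 16.4 (SD, n = 5). That mean did not differ detectably from 50% (exact two-sided sign-flip test, p = 0.375, where the smallest possible p is 0.063), and 1 of 5 animals lay above it. The animals differed from each other by more than their counting intervals. The first 62 X SNPs, at 7131 to 439632, had both alleles in males as well, with 59.6% horse allele in the male mule and 57.6% in the hinny. Beyond these, at 3699662 and further, the shares were 98.0% and 5.11%.

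**Figure D3:**
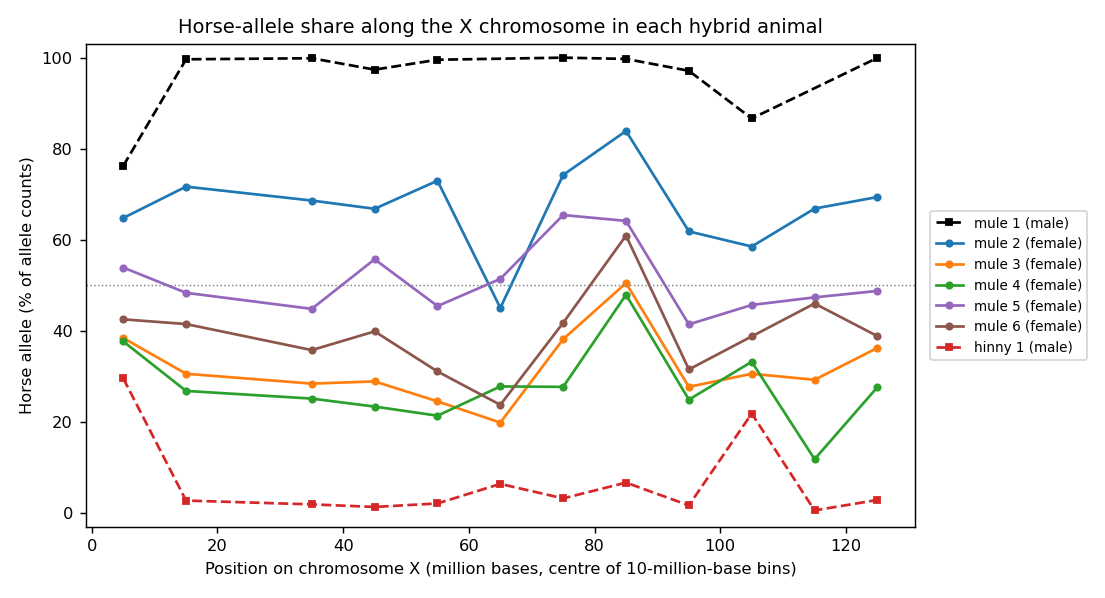
Horse-allele share, in percent of allele counts, along the X chromosome in bins of equal length with at least 50 counts. Solid lines are the 5 female mules, and dashed lines the male mule and the male hinny, which lie on opposite sides of 50% in every bin drawn for both and come nearest to it in the first bin and in the bin at 100000001 to 110000000 (86.6% and 21.9%).

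The comparison of donkeys with horses asks which transcripts differ in total level between the species. Of 49764 nuclear SNPs tested, 637 were higher in donkeys and 764 higher in horses, in 309 and 465 loci. The strongest difference lay on chromosome 12, where all 10 tested SNPs at 30664012 to 30670112 were higher in donkeys, with log2 fold changes of 5.72 to 7.87. Together they took 5280 ± 1367 (SD, n = 3) counts per 1000000 nuclear counts in donkeys and 35.6 ± 28.4 (SD, n = 5) in horses. Mules had 2893 ± 404 (SD, n = 6) and the hinny 2063. The horse allele made up 4.94% ± 2.13 (SD, n = 6) of the segment's counts in mules and 4.29% in the hinny, so the donkey allele was the higher one in both crosses.

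**Figure D4:**
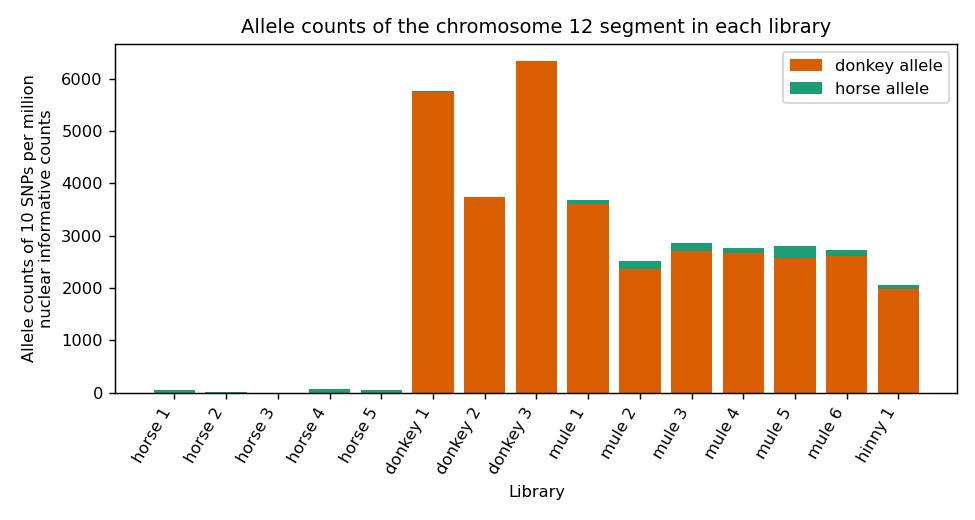
Counts of the 10 SNPs at 30664012 to 30670112 of chromosome 12 per 1000000 nuclear informative counts in each library, stacked by allele. The donkeys reach 3739 to 6344, the mules 2520 to 3683, and the horses at most 64.5.

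Of the 8 named SNPs higher in donkeys, 7 lay in that segment. The other, at 40819906 of chromosome 5, had a log2 fold change of 7.49 (SE 0.963, adjusted p = 0.00036151), with 3.53% ± 5.04 (SD, n = 6) horse allele in mules. The 8 named SNPs higher in horses were spread over the genome. The deepest of them, at 33878483 of chromosome 27, held 46253 pooled counts in horses and 845 in donkeys, a log2 donkey over horse of -5.25 (SE 0.961, adjusted p = 0.0059143). Its horse allele made up 85.5% ± 8.55 (SD, n = 6) in mules and 74.98% in the hinny. The largest fold, -6.21 (SE 0.927, adjusted p = 0.0012432), was at 144492271 of chromosome 1. Of the 8 named horse-higher SNPs, 5 lost the call with sex as a covariate and 7 with day 33 libraries only, which keep 1 horse. The SNP of chromosome 27 was among both, whereas the 8 named donkey-higher SNPs kept their calls in these fits.

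These counts depended on single libraries. They were 1918 and 1950 without horse 1, the only male and day 33 horse, 416 and 488 without horse 2, 276 and 300 without horse 4, and 285 and 338 without horse 5. They were 263 and 245 without donkey 1, 487 and 314 without donkey 2, and 111 and 51 without donkey 3. With sex as a covariate they were 354 and 185, and with day 33 libraries only 42 and 31.

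Total levels in mules differed detectably from the mean of the parental species at 2 of 49764 SNPs, both in the chromosome 12 segment, at 30664119 and 30664228, where mules were higher by log2 2.84 (SE 0.437) and 2.80 (SE 0.419), with adjusted p = 0.033903 for both. This mean is taken on the log scale. On the count scale the parental mean of the segment was 2658 per 1000000, against 2893 ± 404 (SD, n = 6) in mules. DESeq2 called 70 SNPs, and 3493 had an unadjusted p under 0.05 in edgeR. In simulated data 40.4% of changes of log2 2 were recovered in this contrast, so most changes of that size or smaller would go uncalled. With edgeR, no call was made with sex as a covariate or when any donkey or any mule was left out, whereas 14, 17, 5 and 4 were made without horse 1, 3, 4 and 5.

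The hinny did not differ detectably from mules in total level at any SNP with edgeR, where 2963 SNPs had an unadjusted p under 0.05 and DESeq2 called 227. In simulated data 38.8% of changes of log2 4 were recovered in this contrast and 4.04% of changes of log2 2, so changes of that size or smaller would rarely be called. Without mule 1, 264 SNPs were called. Mule 1 and the hinny, the 2 male hybrids, shared the absence of mitochondrial counts, and the hinny correlated more with mule 1 (Pearson r = 0.818 over SNPs) than with the other mules (0.635 to 0.793).

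The ratio between species was compared with the ratio of alleles within mules to separate differences carried by the alleles from those of the cell environment. In mules the donkey allele is always the paternal one, so differences by parent enter this comparison too. SNPs with such differences, as in the clusters of chromosome 12, were not left out. A donkey allele absent from the donkey parents would also make the horse over donkey ratio smaller between species than between alleles. For example, at 723597 of chromosome 16, outside the parental clusters, the log2 ratio was -0.212 between species and 10.74 between alleles. The parents' genotypes were not analysed here, so the calls cannot be read as a count of effects of the cell environment. At 936 of 43337 SNPs the species differed, and 825 of these (88.1%) had the same sign between the alleles of mules. Only 200 of the 936 were also called between the alleles, 196 of them with the same sign. At the median of the 936, the log2 ratio between alleles was 36.4% of that between species. The 936 were chosen by their ratio between species, so this comparison of sizes is not an even one. Agreement in sign does not show that the alleles carry the whole difference. Across all SNPs, which are not independent replicates, the Pearson correlation was 0.302. The 2 ratios differed significantly at 303 SNPs, with a larger horse over donkey ratio between species at 74 and a smaller one at 229. With counts summed over each locus, 12 and 20 loci were called. Of 100 regroupings of the libraries and alleles, the real one included, 6 gave at least 303 SNPs. The lowest adjusted p, 2.9343e-12, was at CUHSNP00007390 in the maternal cluster at 30527666 to 30529524 of chromosome 12. There the log2 ratio of horse over donkey was -1.21 between species (adjusted p = 0.22047) and 13.62 between the alleles of mules. The count of 74 was 158 without horse 1, 45 without donkey 2, 35 without donkey 3, and 49, 48 and 43 without mule 2, 3 and 6.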

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

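The tests of the paternal SNPs with horse allele alone in the hinny were chosen only after the result was seen, whereas the regrouping of libraries was planned.

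At 40 SNPs in 30 loci called paternal, the hinny had 100% horse allele while the mules kept more than 10%, with a mean of 39.5%. Silencing of the maternal allele along the locus would raise the horse share at neighbouring SNPs too, but over all other SNPs of these loci it was 48.3%, and under 60% in 23 of the 29 loci with other SNPs, which argues against it there. For those loci a donkey mother that carried the horse base at single SNPs may be the source. The median hinny share was 45.9% over the 370 other SNPs of all 29 loci. In 4 loci the other SNPs stood at 82.2% to 99.2% in the hinny, and the mules stood at 39.3% to 58.0% there. Silencing to the same degree in mules would give 0.848% to 17.8%, and the mules lay at least 2.79 SD (n = 6) above that. The called SNPs of these loci had, however, been chosen for more than 10% horse allele in mules and for horse allele alone in the hinny. That distance was therefore partly fixed in advance, and it cannot decide about such silencing. Also open are silencing to a lesser degree in mules or beside a difference between the species, and a mother that carried the horse base along the locus. These cannot be told apart at the 4 loci, which were chosen by the hinny's share. The mother's genotype was not analysed here.

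Across 22 groups of values tested for an outlying sample, 2 had one, and chance gives about 1 in 20. Mule 1 had 3683 counts per 1000000 in the chromosome 12 segment that was higher in donkeys, against 2520 to 2861 in the other mules. Horse 1 had 0.0691% donkey allele, against 0.0118% to 0.0248% in the other horses.

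The horse over donkey ratio differed between mules and the hinny at 145 SNPs, by a test of the difference itself. It differed between the species and the alleles of mules at 303 SNPs. Of 100 regroupings of the libraries and alleles, the real one included, 6 gave as many, and the highest of the others gave 1496. Each of the other 5 kept the alleles of at least 5 of 6 mules on a common side, so real allelic differences enter them, and chance is neither excluded nor supported by this regrouping.

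At the 5338 SNPs that the mule lists leave out, the hinny had 38239.5 counts, of which 25.4% were horse allele. The horses had 88.4% to 89.7% horse allele there and the donkeys 2.46% to 4.605%. These SNPs enter no comparison of mules.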

How the results depend on the processing

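Sums over loci, the deepest SNP of each locus, isolated zeros, the parts of the X chromosome, deepest SNPs left out, and horses with donkeys alone were tests chosen only after the data were seen. No analysis that pairs libraries was possible because replicate numbers follow accession order and pair no samples. The alleles of an animal were paired by the animal term of the allelic and parental tests. Lists of imprinted genes, X inactivation genes, pathways and cell type markers, and the deepest SNP of each gene, were not run without gene names.

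For the named SNPs, 334 of 334 values of the allelic ratio in mules kept their direction and call, as did 234 of 236 for mules against the hinny, 327 of 366 for donkeys against horses and 22 of 44 for mules against the parental mean. The others lost the call, and none reversed. Unless the setting itself leaves fewer SNPs or libraries, the cause was not tested.

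The autosomal horse share of mules was 50% as a median over SNPs and 50.53% without the 1% deepest SNPs, and 52.2% to 52.4% when each mule was left out. The X share of female mules ran from 36.6% to 46.8%.

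For alleles within mules, horse-higher and donkey-higher counts were 186 and 234 with the deepest SNP of each locus and 452 and 491 with locus sums. Leaving out a mule gave 594 to 1192 and 474 to 1065, with 739 and 605 without mule 2, 594 and 474 without mule 3, and 682 and 556 without mule 6.

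For mules against the hinny, no minimum on counts gave 64 maternal and 98 near-complete SNPs. The deepest SNP of each locus gave 11 paternal, 7 maternal and 9 near-complete, and locus sums 10, 11 and 11. Fisher's exact test on pooled counts, which ignores the spread between animals, called 735 paternal and 503 maternal. Leaving out a mule gave 55 to 75, 27 to 36 and 48 to 56.

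For donkeys against horses, donkey-higher and horse-higher counts were 1565 and 2900 with DESeq2, 354 and 185 with sex, 42 and 31 at day 33, 1078 and 1442 with every listed SNP, 183 and 211 with locus sums, and 111 and 101 in horses and donkeys alone. Leaving out 1 library gave 111 (donkey 3) to 1918 (horse 1) and 51 (donkey 3) to 1950 (horse 1). They were 416 and 488, 276 and 300, and 285 and 338 without horse 2, 4 and 5, and 263 and 245, and 487 and 314 without donkey 1 and 2.

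For mules against the parental mean, calls numbered 70 with DESeq2, 0 with sex (edgeR), 1 at day 33, 8 with every listed SNP and 0 with locus sums, where 882 loci had an unadjusted p under 0.05. Leaving out 1 library gave 0 (each donkey and each mule) to 17 (horse 3), with 14, 5 and 4 without horse 1, 4 and 5. For the hinny against mules, calls numbered 227 with DESeq2, 3 with every listed SNP and 264 without mule 1.

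For species against alleles, the larger class numbered 301 with DESeq2, 8 with the deepest SNP of each locus and 12 with locus sums, and the smaller class 22 and 20 in the latter pair. Leaving out 1 library gave 35 (donkey 3) to 158 (horse 1), with 45 without donkey 2 and 49, 48 and 43 without mule 2, 3 and 6, and 183 to 313 for the smaller class. Depth limits mule 1, with a median of 4 counts per informative SNP.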

Other observations

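The lists of loci, the tests of the X chromosome and the tests of the autosomal share were chosen only after the results were seen, whereas the regroupings of libraries were planned.

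At 14 loci with unequal alleles in mules, the allele of the same species made up at least 90% of counts in mules and in the hinny, 8 with the donkey allele and 6 with the horse allele. Lone SNPs at 4794573 of chromosome 14 and 23414379 of chromosome 7 had 100% horse allele in both crosses. There a donkey allele absent from the donkey parents cannot be told from a silent allele. The horse allele made up 90.7% of counts in mules and 96.5% in the hinny over 18 SNPs at 22416601 to 22422388 of chromosome 2. It made up 93.4% and 97.3% over 13 SNPs at 31269904 to 31275264 of chromosome 25. Over 7 SNPs at 66634051 to 66657164 of chromosome 1 it made up 6.97% and 7.27%.

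Sums over loci also called 3 near-complete parental switches outside the clusters of called SNPs. At 38235267 to 38241057 of chromosome 4, over 13 SNPs, the horse share was 1.05% in mules and 100% in the hinny. At 109732539 to 109732614 of chromosome 1, over 2 SNPs, it was 3.14% and 100%. At 42690018 to 42696212 of chromosome 24, over 9 SNPs, it was 95.1% in mules and 0 of 52 counts in the hinny, which allows up to 5.77%. With a lone mule standing in for the hinny, 0 to 26 SNPs were called, at most 1 of them near-complete (mule 4).

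Of 238 X SNPs with at least 10 counts in every female mule, 10 had more horse allele in all 5 and 11 more donkey allele in all 5. Of the 10, 9 lay at 87029334 to 87031654, with means of 65.5% to 92.7%. The other, at 100652789, had 50.7% to 60.8% horse allele in the female mules, 53.9% in the male mule and 57.4% in the male hinny. Both males had both alleles at this SNP, so it is no measure of X inactivation.

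The horse share of the X chromosome ran from 27.9% to 68.7% over the female mules. Without the 10 deepest SNPs the range was 41.9 percentage points, which argues against a few abundant SNPs. Mapping in favour of the reference allele would hold every female at or above 50%, but 3 lay below it by more than the counting interval on both sides of the chromosome's middle. Beyond the first 1.5 Mb, the parts before and after the middle differed by at most 8.67 points within an animal, against a range of 41.8 points between animals, so a different balance of the inactive X in each animal may be the source, which stays a hypothesis.

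The autosomal horse share of mules fell from 52.3% to 50.53% ± 0.138 (SD, n = 6) without the 487 deepest SNPs, which held 28.6% of counts. A few abundant SNPs could therefore account for most of the excess, but the remainder lies too near the bound set for this test to decide. The maternal cluster at 30527666 to 30529524 of chromosome 12 held 354244 mule counts with 99.9% horse allele. In the hinny it held 80196.5 counts with 3.12% horse allele. This cluster thus raises the share of mules and lowers that of the hinny, and the shares without it were not computed. With each SNP counted once the mean share was 50.2% ± 0.154 (SD, n = 6), which argues against mapping in favour of the horse allele as the whole cause in mules. In the hinny that mean was 51.5%, in the direction such mapping would give, so a smaller part stays open. SNPs with horse allele alone in the hinny, such as the 40 flagged above, raise its mean as well, and by how much was not computed. No biological explanation was tested. The mean over SNPs replaced the median first computed for this test, which was 50% in every mule and so had no spread. The bound of the test was rewritten then.

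Regrouping was run for 3 counts besides that of species against alleles, and under 5% of the regroupings gave as many in each. The 145 SNPs of mules against the single hinny were not regrouped. Of 32 exchanges of alleles within mules, 1, the real one, gave 2373 SNPs, and the highest other gave 9. Of 56 splits of horses and donkeys, 1, the real one, gave 1401, and the highest other gave 510. That split grouped horse 1, horse 3 and donkey 2, the libraries with the fewest SNPs detected in their species (80.9%, 78.4% and 75.1% with a count). Whether detection gave the calls of that split was not tested. For mules against the parental mean, 3 of 100 gave as many as the 2 real calls, and the highest other gave 6. These regroupings mix horses, donkeys and mules, so differences between the species enter the spread within groups. They therefore cannot decide whether the 2 calls arose by chance.

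Mule 1 and the hinny shared 0 mitochondrial counts. The hinny also had 67 SNPs at 0 beside a well covered neighbour within 10 bases, against 0 to 9 in the other libraries.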
